A study of Mus musculus with 18 samples.

How the data were processed

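Gene expression was measured by RNA sequencing of whole testis from ICR mice, an outbred strain, at 10 weeks of age. Per the labels' protocols, testes were snap-frozen, RNA was taken up in Trizol and purified on a column, and Illumina libraries were made from 1 µg of total RNA. The labels give 6 groups of 3 libraries each. The labels say no more of the control group than its name. The AOS group received alginate oligosaccharide, short sugar chains cut from brown algal alginate, at 10 mg/kg. The STZ group received streptozotocin, a compound toxic to pancreatic beta cells that is used to make mice diabetic. The STZ + AOS group received both. The last 2 groups received streptozotocin and a faecal microbiota transplant (FMT), read here from the labels as material from donors given AOS at 10 mg/kg (AOS-transplant group) or from control donors (control-transplant group). The labels do not say whether the libraries of a group come from separate animals, so the p-values measure only the spread between these samples.

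The deposited table has 1 value per gene and library, and its header names no unit. The authors' values were taken as FPKM (fragments scaled by transcript length and by library depth) because the low values of a gene are whole multiples of a step that falls with transcript length. Within a tolerance of 0.15, 82.4% of the 2642 low values examined were whole multiples of their step. The step was taken from the lowest values of each gene, which are near whole by construction. In 123 genes all values were whole, and only these were used for the step sizes below. RPKM gives the same pattern and cannot be distinguished, and TPM with some genes left out is not excluded. The submitters' processing notes name Bowtie 0.12.2, a short-read aligner, and the genome build mm10, without a role for either. Bowtie places reads without gaps, so the yield of reads across exon junctions depends on what the reads were aligned to. The counter, the annotation and the scaling tool are not given in the sources used here.

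The number of reads per library is not known from the table. The size of the step gave a relative depth between 0.912 (STZ replicate 1) and 1.027 of the average library, so the 18 libraries had similar depth. No counting interval or detection floor was computed. Pearson correlations of log2 values between replicates of a group ranged from 0.9782 to 0.9946, and at most 0.81% of the values of a pair of replicates were identical. Of 20985 genes in the table, 20247 (96.5%) matched a GENCODE M21 symbol, from which GRCm38 (mm10) coordinates, transcript lengths and GC contents were taken. The table also holds 26 symbols turned into dates by a spreadsheet, 11 turned into plain numbers and 395 genes at 0 in every library. These were kept, but none is named.

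Tests used limma 3.58.1 in R 4.3.3. Because the values are in a normalized unit, the branch of the design for normalized values was used: limma-trend on log2(value + 1) of the values as deposited, for the 14164 genes with a value of at least 1 in at least 3 of the 18 libraries. All 18 libraries entered 1 model with a mean per group and no replicate block. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison, and all tests but the F test were two-sided. The design compared STZ with control, AOS with control, each of the 3 treated STZ groups with STZ, and the transplant groups with each other. It also tested the effect of AOS with STZ minus that without STZ (the interaction), and any difference among the 6 groups (F test). Comparisons of the 3 treated STZ groups with control, and of STZ + AOS with AOS, were added after seeing the data. These choices, the gene lists and the naming rule were made before the data were examined, except where stated otherwise.

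For 31 gene lists of testis cell types, neighbouring tissues, blood, immune, stress and metabolic pathways, members were compared with all other genes by camera, with a preset correlation of 0.01 and again with an estimated correlation, and tested for a shared direction by fry. Adjusted p for lists cover the 29 lists with at least 5 measured members. The lymphocyte list (2 measured) and the list of mitochondrially encoded genes (0 measured) were not tested. Genes were named by rule: per comparison, the 8 genes with the largest increase and the 8 with the largest decrease among called genes whose 3 and 3 libraries did not overlap and whose mean was at least 1 in a group. Up to 4 members with the smallest p were added from each list that passed or held a called gene, and the values of a fixed set of marker genes were always given. Where fewer than 10 genes were called, the 5 with the smallest p in each direction were named. Non-overlap was not required for the interaction, which has 4 groups. Genes outside the rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

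The model and the list test were run first on simulated data made from these libraries' means and spread, with 200 genes changed. In simulated STZ against control libraries, 66% of genes changed by a log2 of 0.5, 92% at 1 and 99% at 2 were recovered, with 12, 7 and 19 false calls. For the transplant groups the shares were 66%, 95.5% and 100%. With no genes changed, 0 genes were called in either. A simulated shift of the Sertoli list by 0.5, 1 or 2 was recovered by camera, and no shift gave an adjusted p of 0.874. Of the other lists, 1 also passed at a shift of 0.5 and 0 at 1 and 2.

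The alternatives set beforehand were quantile normalization, no low-value filter, a pseudocount of 0.1, array weights, only the groups compared, the replicate number as a block, and leaving out each replicate. Median centring, a correction for transcript length and GC content, and leaving out 3 libraries with epididymal transcripts (control replicate 3 and control-transplant replicates 2 and 3) were chosen after seeing the data. Values are given as mean ± SD in FPKM with n = 3 per group, and log2 fold changes (log2FC) are from the model, with their standard error (SE). Tables were prepared with Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.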

Results

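Transcript levels were measured in 18 testis libraries, 3 from each of 6 groups of mice: control, AOS, STZ, STZ + AOS, and the STZ groups transplanted with faecal microbiota from AOS-dosed or from control donors. Values were in FPKM, and the sums over all genes ranged from 561038 to 622169 per library. The protamine and transition protein genes, which package DNA in late spermatids, took 7.25 ± 0.43% of the sum in control libraries and 4.88 ± 1.52% in STZ libraries (SD, n = 3 each). In the other 4 groups this share lay between 7.28 ± 0.38% (STZ + AOS) and 8.58 ± 0.13% (AOS). Genes at 1 FPKM or more made up 66.73 ± 1.5% of the table in STZ libraries and 62.2 to 63.57% on average in the other groups. The first principal component carried 54.2% of the variance and set the 3 STZ libraries, at 26.2, 60.9 and 61.8, apart from the 15 other libraries, which lay between −16.2 and −1.9. STZ replicate 1 lay nearest to the other groups. An F test found differences among the 6 groups in 7409 of 14164 genes.

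**Figure D1:**
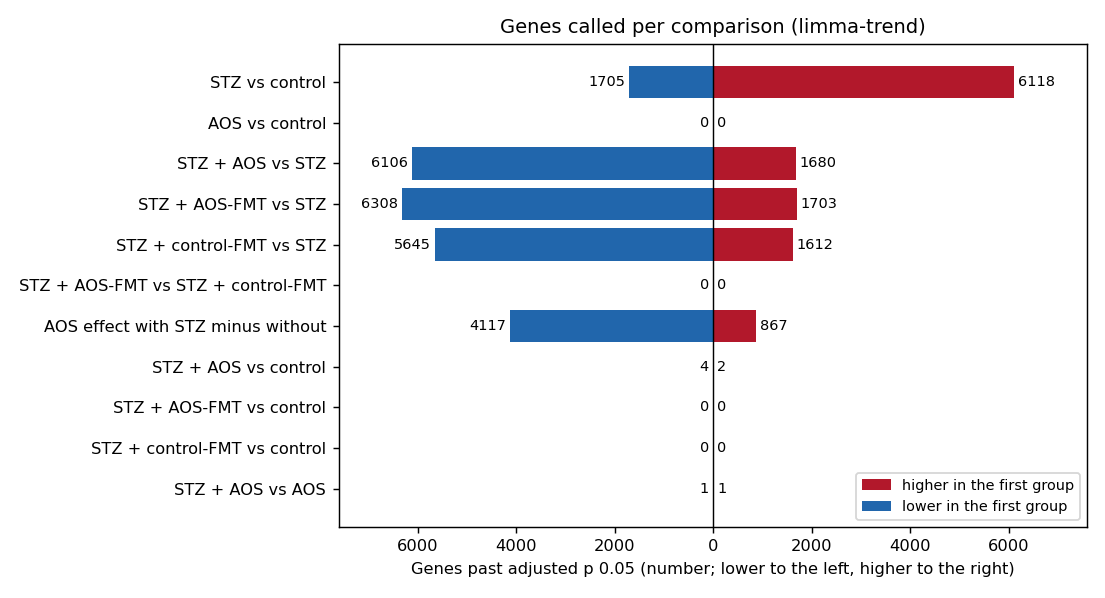
Number of genes past adjusted p 0.05 in each comparison (limma-trend, 14164 genes, 3 libraries per group), with genes higher in the first-named group to the right and lower to the left. STZ against control gives 6118 higher and 1705 lower genes on the deposited scaling, and 3156 and 4093 after quantile normalization, while AOS against control and the 2 transplant groups against each other give 0.

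The first question was what streptozotocin did to the testis transcriptome. Testes of STZ mice had higher levels of Sertoli cell and macrophage genes and lower levels of late spermatid genes than control testes. Clu, which encodes the glycoprotein clusterin secreted by Sertoli cells, was at 1409 ± 177 FPKM in STZ and 483.7 ± 29.3 FPKM in control libraries (log2FC 1.53, SE 0.08, adjusted p = 3.7e-09). The lysozyme gene Lyz2 of macrophages was at 79.37 ± 16.9 and 17.9 ± 0.968 FPKM (2.07, SE 0.18, adjusted p = 4.1e-07). Prm2, a protamine gene of elongating spermatids, was at 6315 ± 2040 and 11440 ± 1360 FPKM (−0.9, SE 0.18, adjusted p = 0.00078). For each of these genes the 3 STZ libraries did not overlap the 3 control libraries.

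Among the somatic cells of the tubule, Sertoli genes moved most uniformly. Of 26 measured Sertoli genes, 25 rose in STZ and 0 fell, with the same 25 adjusted over the list alone and a median log2FC of 1.14 (0.97 above the median of all genes). The list passed camera (adjusted p = 1.28e-09; adjusted p = 0.316 with an estimated correlation). It included the tight junction gene Cldn11 (109.5 ± 15.3 against 33.14 ± 0.934 FPKM, adjusted p = 2e-09), the transcription factor genes Wt1 (log2FC 1.2) and Sox9 (9.297 ± 1.95 against 2.903 ± 0.4 FPKM, 1.39), and the intermediate filament gene Vim (1.83). Of 18 genes of the blood-testis barrier, the junction between Sertoli cells that closes off the tubule lumen, 16 rose and 2 fell, the same adjusted over the list alone (median 0.76, camera adjusted p = 0.000416; adjusted p = 0.284 with an estimated correlation). F11r, which encodes a junctional adhesion molecule, rose by 1.28 and the vinculin gene Vcl by 0.93. Retinoic acid genes behaved alike: 13 of 20 rose and 0 fell, also adjusted over the list alone (median 0.51, camera adjusted p = 0.0148; adjusted p = 0.367 with an estimated correlation).

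Germ cell genes split by stage. Of 29 elongating spermatid genes, 25 fell and 0 rose, or 28 fell adjusted over the list alone (median log2FC −0.51, or −0.68 relative to all genes; camera adjusted p = 1.8e-14; adjusted p = 0.316 with an estimated correlation). The STZ libraries differed in this, with list medians of −0.09, −0.84 and −0.56 relative to control, and the median log2FC was −0.33 without STZ replicate 2. Smcp, which encodes a protein of the sperm mitochondrial capsule, fell from 4693 ± 166 to 2909 ± 425 FPKM (log2FC −0.7, adjusted p = 1.3e-05), and Oaz3 and Spata18 fell by 0.65 and 0.7. Prm1 fell from 12800 ± 1040 to 8561 ± 3180 FPKM with overlapping libraries (log2FC −0.64, adjusted p = 0.0067), and Tnp1 from 6431 ± 376 to 4581 ± 1360 FPKM (−0.53, adjusted p = 0.01). Neither call of these last genes held when only the STZ and control libraries were fitted, nor did that of Prm1 after quantile normalization. Of 28 round spermatid genes, 24 fell and 0 rose, or 25 fell adjusted over the list alone (median −0.22, camera adjusted p = 2.27e-11; adjusted p = 0.284 with an estimated correlation), but without STZ replicate 3 only 11 fell (median −0.18). Tssk3, a kinase gene of spermatids, was at −0.47, and Acrv1, an acrosomal gene, at −0.21 (259.2 ± 23.8 against 298.9 ± 9.18 FPKM, adjusted p = 0.019), but that call ended without control replicate 3, without STZ replicate 3 and after quantile normalization. Of 37 sperm motility genes, 25 fell and 0 rose, or 30 fell adjusted over the list alone (median −0.2, camera adjusted p = 5.13e-13; adjusted p = 0.235 with an estimated correlation), among them the sperm calcium channel gene Catsper1 (−0.38) and the sperm adenylyl cyclase gene Adcy10 (−0.36). Without STZ replicate 3 only 14 of these fell (median −0.15).

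Earlier germ cells gave a mixed picture. Of 18 spermatogonial genes 14 rose and 1 fell, the same adjusted over the list alone (median 0.53), but the list did not pass camera (adjusted p = 0.0591). It passed without STZ replicate 2, after median centring (median 0.19) and with no low-value filter or a replicate block. Stra8, which is induced by retinoic acid ahead of meiosis, rose from 7.763 ± 1.77 to 19.59 ± 2.4 FPKM (log2FC 1.25, adjusted p = 9.7e-06), Uchl1 by 1.04 and the receptor gene Kit by 0.74 (9.58 ± 2.37 against 5.28 ± 1.14 FPKM). Zbtb16 was at 1.393 ± 0.38 and 0.63 ± 0.121 FPKM (0.54, adjusted p = 0.0013), a call that ended after quantile normalization, median centring and the length and GC correction. Of 39 meiotic genes 5 rose and 7 fell, or 4 and 6 adjusted over the list alone. The median was 0.03 while camera pointed down (adjusted p = 0.0192; adjusted p = 0.47 with an estimated correlation), and the median was −0.13, −0.32 and −0.13 under the same 3 scalings in turn. Without STZ replicate 1 this list no longer passed. Ccna1 (cyclin A1) fell by 0.5 and the bromodomain gene Brdt by 0.29, and the recombinase gene Dmc1 was at 0.4 (7.68 ± 0.648 against 5.55 ± 0.32 FPKM) but at 0.02 after quantile normalization. Sycp3, a gene of the synaptonemal complex, did not pass the test (194.7 ± 21 against 189.6 ± 5.49 FPKM, adjusted p = 0.78). Of 5 replication histone genes 1 fell, also adjusted over the list alone (Hist1h4a, −0.37), with camera adjusted p = 0.103.

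Immune genes were higher in STZ testes. Of 18 macrophage genes 14 rose and 1 fell, the same adjusted over the list alone (median log2FC 1.05, camera adjusted p = 0.00397; adjusted p = 0.47 with an estimated correlation). The gene of the MHC class II invariant chain, Cd74, was at 79.99 ± 34.1 against 9.72 ± 0.459 FPKM (log2FC 2.82), the complement gene C1qa at 26.07 ± 11.2 against 6.757 ± 0.662 FPKM (1.71), and Cd68 rose by 1.49. Adgre1, which encodes the macrophage marker F4/80, did not pass (2.163 ± 0.994 against 1.37 ± 0.03 FPKM, 0.36, adjusted p = 0.12). All 11 measured interferon response genes rose, also adjusted over the list alone (median 1.04, camera adjusted p = 0.0177; adjusted p = 0.575 with an estimated correlation), with Bst2 (tetherin) at 1.38. Of 13 genes of NF-κB inflammation 8 rose and 0 fell, the same adjusted over the list alone, with Saa3 at 2.65 and Nfkbia at 1.32, without the list passing camera (median 0.51, adjusted p = 0.0977), though it passed without STZ replicate 1 and under each of the 3 other scalings (medians 0.25, 0.16 and 0.22).

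Lists of other interstitial cells did not pass on the deposited scaling with all libraries in the model. Of 27 Leydig cell genes 9 rose and 3 fell, or 8 and 3 adjusted over the list alone. The list's median was 0.25 while camera pointed down (adjusted p = 0.677), and the median was −0.1 after median centring, 0.69 without STZ replicate 1 and 0.14 without STZ replicate 3. Tspo (1.34), Nr5a1 (1.23), Hsd11b1 (1.26) and Cyb5a (1.04) rose, whereas Star (50.2 ± 30.4 against 44.48 ± 7.68 FPKM, adjusted p = 0.88), Cyp17a1 (374.3 ± 276 against 348 ± 36.1 FPKM, 0.61), Hsd3b1 (151.9 ± 84.5 against 71.18 ± 9.17 FPKM, 0.057) and Insl3 (7993 ± 5560 against 3144 ± 208 FPKM, 0.14) did not pass. The STZ libraries disagreed on these genes: the Leydig list median relative to control was −0.44 in STZ replicate 1 and 0.57 and 0.85 in replicates 2 and 3, and without replicate 1 Insl3 was at 1.83, Hsd3b1 at 1.44 and Star at 0.6, all past the threshold, as were 19 list members upward. Of 11 peritubular myoid genes 9 rose and 1 fell (median 0.81, camera adjusted p = 0.0942; Myl9 at 1), of 14 endothelial genes 11 rose and 0 fell (0.6, 0.0743; Pecam1 at 0.82), and of 14 fibroblast genes 7 rose and 0 fell (0.46, 0.0808; Dcn at 1.83 and Sparc at 1.43), with the same counts adjusted over each list alone. The fibroblast list passed without STZ replicate 1 (median 0.78, 11 higher) and was at 0.24 without STZ replicate 3. Under the 3 other scalings the myoid (medians 0.41, 0.47 and 0.52) and fibroblast lists (0.14, 0.11 and 0.2) passed, and the endothelial list did after median centring (0.26).

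Markers of tissue that a dissection can include were checked as well. Of 6 erythrocyte genes 1 rose, also adjusted over the list alone (Alas2, 0.52, a call lost after median centring), with the list at a median of 0.53 and a camera adjusted p of 0.677 pointing down. Its median was 0.97 without STZ replicate 1 and −0.17 without STZ replicate 2. Hba-a1 was at 196.6 ± 168 against 98.97 ± 12.4 FPKM and Hbb-bs at 2.22 ± 2.74 against 7.523 ± 10.1 FPKM, neither past the test (adjusted p = 0.4 and 0.5). Of 8 epididymis genes, Wfdc10 rose (1.31) and Cst8 was at −0.31 (adjusted p = 0.041), or only the first adjusted over the list alone (median −0.11, or 0.13 without STZ replicate 2; camera adjusted p = 0.277). Of 9 adipose genes only Lpl passed (1.03), or 0 adjusted over the list alone (median 0.67, camera adjusted p = 0.864 pointing down). The adipose median was 1.1, 1 and −0.08 without STZ replicates 1, 2 and 3 in turn, and the Lpl call ended without STZ replicate 3, the library with the highest adipose list median (2.18 relative to control).

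Stress and ribosomal genes were divided between lists that passed camera in STZ and lists that did not. Of 20 immediate early and heat shock genes 16 rose and 1 fell, or 17 and 1 adjusted over the list alone (median 0.98, camera adjusted p = 0.0093; adjusted p = 0.47 with an estimated correlation), with the small heat shock protein gene Hspb1 at 78.63 ± 3.73 against 24.51 ± 2.07 FPKM and Junb at a log2FC of 1.54. Of 24 genes of apoptosis and p53 response 19 rose and 0 fell, also adjusted over the list alone (0.57, camera adjusted p = 0.00594; adjusted p = 0.432 with an estimated correlation), including Gadd45a (1.43) and Casp8 (1.3). Of 34 ribosomal protein genes 32 rose and 0 fell, the same adjusted over the list alone (0.38, camera adjusted p = 1.38e-05; adjusted p = 0.385 with an estimated correlation), although the median was 0.04 after median centring. The X-linked members Rps4x (101.8 ± 16.8 against 34.96 ± 8.56 FPKM, 1.53) and Rpl10 (1.29) changed most among the members named, and Rpl3 rose by 0.68. Antioxidant genes (21 of 34 rose and 2 fell, or 21 and 3 adjusted over the list alone; median 0.44) did not pass camera (adjusted p = 0.151), with Prdx2 at 1.32 and Gsta4 at 1.24. Neither did those of the unfolded protein response (10 of 19 rose and 1 fell, or 12 and 1 adjusted over the list alone; median 0.23, adjusted p = 0.307), whose median was −0.11 after median centring, −0.04 after the length and GC correction and 0.15 without STZ replicate 3 (9 higher). After quantile normalization both lists passed, and the antioxidant list also did so under the 2 other scalings. Xbp1 rose by 1.16.

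Metabolic gene lists did not pass camera with all libraries on the deposited scaling. After quantile normalization fatty acid (median 0.06) and oxidative phosphorylation genes (0.24) passed upward, and glycolysis genes passed downward without STZ replicate 1 and cholesterol synthesis genes without STZ replicate 3 (median −0.04). Glucose transport and glycolysis genes went both ways, with 9 of 31 higher and 9 lower, also adjusted over the list alone (median −0.05, adjusted p = 0.0743): Pfkl (1.54) and Ldhb (1.18) rose and Aldoart1, a sperm aldolase gene, fell by 0.42. Of 20 insulin and IGF signalling genes 12 rose and 1 fell, the same adjusted over the list alone (median 0.37, adjusted p = 0.118), with Igfbp3 at 2.02, and a median of 0.61 without STZ replicate 1 and 0.23 without STZ replicate 3. Of 29 fatty acid genes 15 rose and 3 fell, the same adjusted over the list alone (0.37, adjusted p = 0.456), with Cpt1a at 1.08 and Fasn at 0.84, and a median of 0.56 without STZ replicate 1. Of 33 nuclear genes of oxidative phosphorylation 18 rose and 2 fell, or 19 and 2 adjusted over the list alone (0.21, adjusted p = 0.324), with medians of −0.14 after median centring and −0.03 after the length and GC correction. Of 23 cholesterol synthesis genes 4 rose and 1 fell, or 1 and 0 adjusted over the list alone (median 0.08, camera pointing down, adjusted p = 0.248), and their median was negative under all 3 other scalings (−0.11, −0.26 and −0.18). Without STZ replicate 1 their median was 0.2, with 11 higher and 1 lower, and camera pointed up (adjusted p = 0.532).

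The largest increases were in Bpifa2 (chromosome 2, 154008265 to 154016079), which encodes a secreted salivary-type protein and rose from 0.1067 ± 0.0462 to 18.25 ± 11.9 FPKM (log2FC 3.95, SE 0.31), and in Spp1 (osteopontin; chromosome 5, 104435118 to 104441050), at 56.31 ± 26 against 2.597 ± 0.305 FPKM (3.9, SE 0.29). They were followed by the acute-phase protease inhibitor gene Serpina3n (3.52), Apod (3.39), Gpnmb (3.08), Lrg1 (2.99), the matrix gene Mgp (2.94) and Timp1 (2.92), an inhibitor of matrix metalloproteinases. The largest decreases were in tissue kallikrein genes, a cluster of closely similar paralogs whose reads are hard to assign: Klk1b21 (−2.63), Klk1b24 (22.25 ± 8.02 to 4.677 ± 4.49 FPKM, −2.32; chromosome 7, 44188236 to 44192455), Klk1b27 (−2.09) and Klk1b22 (−1.61). Next were Bhmt (−1.23), which encodes betaine-homocysteine methyltransferase and was not called when only these groups were fitted, the testis histone gene Hist1h2aa (−1.11), Hist1h3d (−0.96), not called without control replicate 1 or 3, and Prm2 (−0.9). The named kallikrein genes also had lower means in AOS without streptozotocin than in control, where no gene passed. Klk1b21 was at 6.803 ± 2.24 in AOS against 21.34 ± 5.28 FPKM in control, and Klk1b24 at 7.5 ± 1.6 FPKM in AOS.

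In total, 7823 of 14164 genes differed between STZ and control at an adjusted p under 0.05 (limma; 8582 at an unadjusted p under 0.05), 813 of them higher and 15 lower by a log2FC of at least 1. Library groups did not overlap for 53.6% of genes, against 10% expected by chance. The balance of directions depended on the scaling: the median log2FC of all genes was 0.172 on the deposited values, −0.062 after quantile normalization, −0.17 after median centring and −0.061 after the length and GC correction, and the calls split into 6118 higher and 1705 lower, 3156 and 4093, 2678 and 6119, and 3484 and 4757 in turn. Sertoli (0.92, 0.8, 0.82) and macrophage (0.77, 0.7, 0.81) medians stayed positive and elongating spermatid medians (−0.35, −0.85, −0.74) negative under the 3 other scalings, and these lists passed in each. Fitting STZ and control alone gave 5132 calls.

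**Figure D2:**
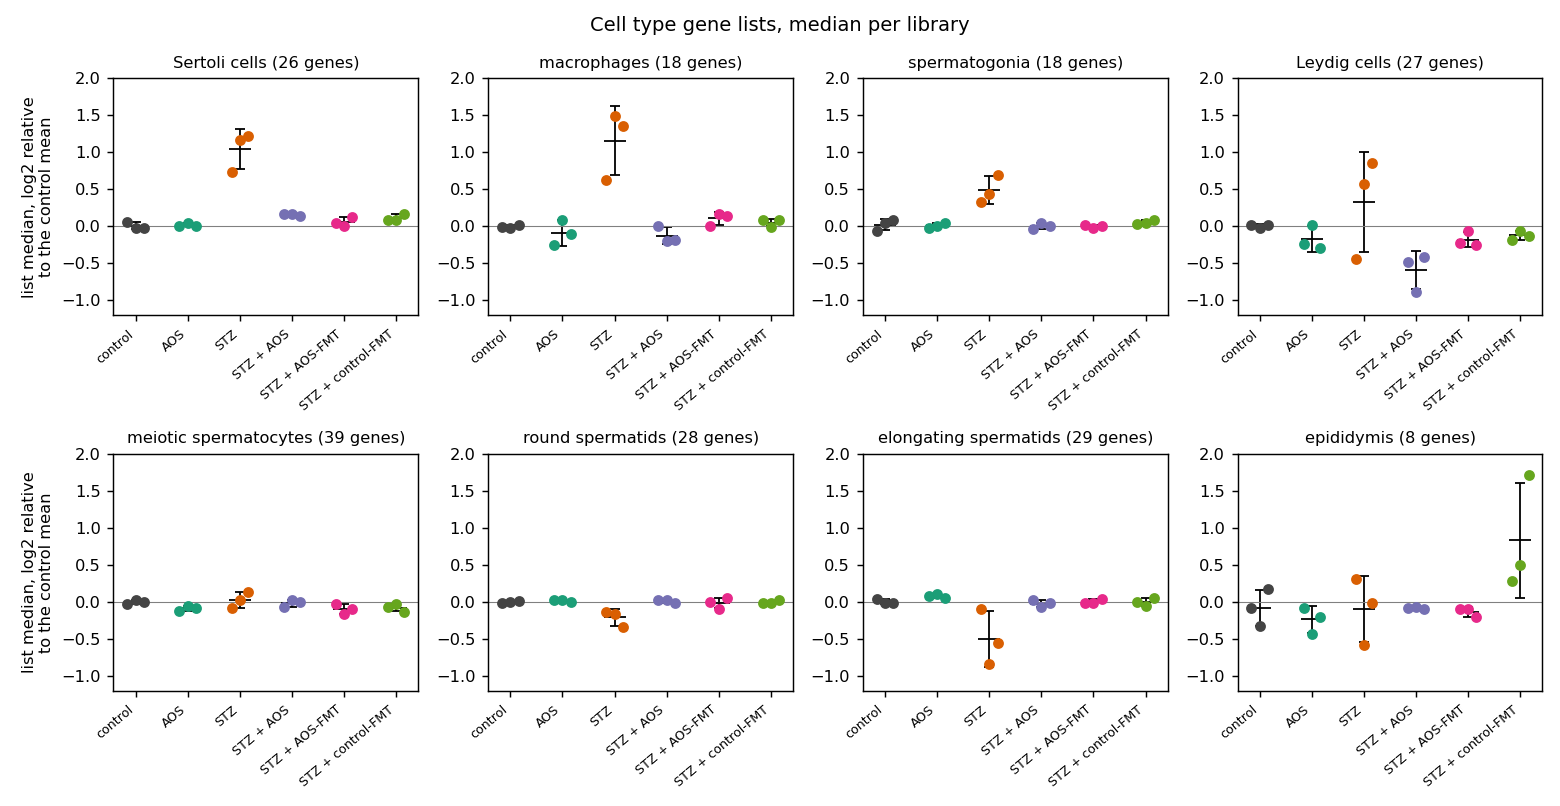
Median log2 value of 8 gene lists in each library relative to the control mean (y axis, log2), with points for libraries, bars for the group mean and whiskers for SD (n = 3). Sertoli medians are 0.73, 1.17 and 1.22 in the STZ libraries and between −0.02 and 0.17 in the others; Leydig medians run from −0.44 to 0.85 within STZ.

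AOS given without streptozotocin was compared with control to see what the compound did on its own. No gene passed the test: limma called 0 genes, with 1273 at an unadjusted p under 0.05 and a smallest adjusted p of 0.407. The genes with the smallest p that were higher in AOS were Hoxa3 (5.99 ± 0.384 against 3.84 ± 0.278 FPKM, log2FC 0.53), Ghrl (ghrelin; 95.35 ± 10.1 against 62.78 ± 4.62 FPKM, 0.59), Tubb2a (0.3), Ankrd60 (0.31) and Tmem89 (0.26). Those lower were Epc2 (−0.26), Fastkd2 (−0.33), Arhgap5 (−0.26), Tax1bp1 (−0.2) and Ascc3 (−0.24), all at adjusted p = 0.41. The markers Clu (474.1 ± 22.5 FPKM), Sox9 (3.217 ± 0.526), Stra8 (9.07 ± 1.27), Kit (4.573 ± 0.481), Zbtb16 (0.67 ± 0.114), Sycp3 (177.5 ± 16.6), Dmc1 (5.633 ± 0.647), Acrv1 (282.4 ± 18.2), C1qa (6.09 ± 0.93), Hba-a1 (67.34 ± 19.7), Hsd3b1 (66.15 ± 20) and Insl3 (2465 ± 418) overlapped the control libraries. Prm1 (15080 ± 732 against 12800 ± 1040 FPKM), Star (33.17 ± 3.19) and Cyp17a1 (255 ± 30.6) did not overlap them but failed the test (adjusted p = 0.72, 0.79 and 0.83).

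Some lists passed camera in AOS against control without a called member. Elongating spermatid genes had a median of 0.07 (adjusted p = 0.000616), oxidative phosphorylation genes 0.01 (0.000616), ribosomal protein genes 0.04 (0.00165), interferon genes 0.19 (0.00596; 0, 0.11 and 0.59 in the AOS libraries, so mostly from replicate 3) and cholesterol synthesis genes −0.2 (0.00235). Adjusted over the list alone, 4 oxidative phosphorylation genes were higher, 1 cholesterol gene was lower and 0 passed in the others. Every one of these had adjusted p = 0.951 with an estimated correlation. The elongating spermatid and ribosomal lists also lost their calls after quantile normalization, where both medians were 0, and with oxidative phosphorylation genes after the length and GC correction. Groups did not overlap for 22.3% of genes, against 10% expected by chance.

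Next, AOS given to streptozotocin-treated mice was compared with streptozotocin alone. The genes that were high in STZ were lower in STZ + AOS, and the spermatid genes were higher. Clu was at 550.3 ± 12.7 against 1409 ± 177 FPKM (log2FC −1.35, SE 0.08, adjusted p = 2.6e-08), Spp1 at 2.31 ± 0.722 against 56.31 ± 26 FPKM (−4.04, SE 0.29), and Prm2 at 10800 ± 761 against 6315 ± 2040 FPKM (0.82, SE 0.18). Of 26 Sertoli genes 24 fell and 0 rose, also adjusted over the list alone (median −1.05, camera adjusted p = 3.6e-08; adjusted p = 0.369 with an estimated correlation). Of 29 elongating spermatid genes 27 rose and 0 fell, the same adjusted over the list alone (0.51, camera adjusted p = 4.81e-14; adjusted p = 0.369 with an estimated correlation), but the median was 0.32, with 17 called, without STZ replicate 2. Of 18 macrophage genes 16 fell and 1 rose, again adjusted over the list alone (−1.52, camera adjusted p = 0.000592; adjusted p = 0.442 with an estimated correlation), with Lyz2 at −2.21 and Cd68 at −1.75. Ribosomal protein genes fell in 32 of 34 cases, also adjusted over the list alone (−0.38, camera adjusted p = 2.32e-05; adjusted p = 0.41 with an estimated correlation).

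Leydig cell genes were lower in STZ + AOS than in STZ, with 20 of 27 down and 1 up, or 21 and 1 adjusted over the list alone (median −1.13, camera adjusted p = 0.0349; adjusted p = 0.618 with an estimated correlation). The list lost this call without STZ replicate 2 or 3. Hsd3b1, which encodes a steroid dehydrogenase, was at 41.26 ± 14.3 against 151.9 ± 84.5 FPKM (log2FC −1.72, adjusted p = 0.0014). Star, which brings cholesterol into the mitochondrion, was at 17.81 ± 6.4 against 50.2 ± 30.4 FPKM (−1.24, adjusted p = 0.015) and Insl3 at 1988 ± 190 against 7993 ± 5560 FPKM (−1.55, adjusted p = 0.015). Both overlapped, and neither passed without STZ replicate 2 or 3. Cyp17a1 did not pass (125.2 ± 50.9 FPKM, −1.23, adjusted p = 0.055). Among germ cell markers, Stra8 (10.12 ± 2.28 FPKM, −0.9) and Kit (4.59 ± 0.703, −0.9) fell, Prm1 (13180 ± 620, 0.69) and Tnp1 (6331 ± 624, 0.51) were higher in the shared model but not when only these groups were fitted, and Sycp3 was at 0.01. Among other markers, Sox9 (3.57 ± 0.217 FPKM, −1.15) and C1qa (6.553 ± 1.05, −1.75) fell, Adgre1 was at 0.9733 ± 0.272 FPKM (−0.63, adjusted p = 0.011) with overlapping libraries, and Hba-a1 (153.3 ± 38.4) was not distinguishable (0.07, adjusted p = 0.93).

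STZ + AOS and STZ differed in 7786 genes (limma; 1680 higher, 6106 lower), with 6 higher and 900 lower by a log2FC of at least 1 and 52.2% of genes not overlapping against 10% by chance. Besides Spp1, the largest decreases were in Bpifa2 (−3.58), Gpnmb (−3.19), Ly6d (−2.85), the macrophage elastase gene Mmp12 (−2.68), Mgp (−2.65), Lrg1 (−2.64) and the galectin gene Lgals3 (−2.58). The largest increases were in Slc14a2 (1.09, not called without STZ replicate 1), Smok2b (0.92), Tcp10c (0.87), Cyp2a12 (0.86), Prm2, Plac9a (0.8), Tppp2 (0.76) and Olfr733 (0.71). The direction split turned to 4242 higher and 3108 lower after quantile normalization, 6319 and 2818 after median centring, and 4980 and 3547 after the length and GC correction, with the median of all genes at −0.168 as deposited and at 0.074, 0.179 and 0.075. With only these groups fitted, 4944 genes were called.

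Mice transplanted with microbiota from AOS-dosed donors were compared with STZ to ask whether the transplant alone went with a changed transcriptome. Sertoli genes fell and elongating spermatid genes rose. Clu was at 489.9 ± 4.35 FPKM (log2FC −1.51, SE 0.08, adjusted p = 4.3e-09), Spp1 at 1.457 ± 0.241 FPKM (−4.45) and Prm2 at 12720 ± 2140 FPKM (1.04, adjusted p = 0.00021). Of 26 Sertoli genes 25 fell and 0 rose, also adjusted over the list alone (median −1.05, camera adjusted p = 2.03e-08; adjusted p = 0.355 with an estimated correlation). Of 29 elongating spermatid genes 25 rose, or 28 adjusted over the list alone, and 0 fell (0.5, camera adjusted p = 3.42e-15; adjusted p = 0.347 with an estimated correlation). Of 18 macrophage genes 14 fell, or 15 adjusted over the list alone, and 1 rose in each case (−1.2, camera adjusted p = 0.0121; adjusted p = 0.602 with an estimated correlation). Leydig genes had a median of −0.57 with 11 lower and 1 higher, also adjusted over the list alone, and did not pass camera (adjusted p = 0.544). The Leydig median was −1.17 without STZ replicate 1, where the list passed, −0.4 without replicate 2 and −0.33 without replicate 3, where camera pointed up. The list also passed after quantile normalization (−0.46) and median centring (−0.21).

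Single markers in the AOS-transplant group against STZ followed the lists. Sox9 (3.653 ± 0.456 FPKM, −1.13), Stra8 (8.713 ± 0.629, −1.08), Kit (4.53 ± 0.173, −0.91) and C1qa (7.237 ± 0.501, −1.62) fell, and Prm1 (14130 ± 856, 0.79) and Tnp1 (6797 ± 212, 0.61) were higher in the shared model, not when only these groups were fitted. Insl3 (2888 ± 130 FPKM, −1.01, adjusted p = 0.093), Hsd3b1 (79.21 ± 11.4, −0.75), Star (28.54 ± 3.31, −0.53), Cyp17a1 (237.6 ± 49.9, −0.23), Sycp3 (170.6 ± 16.7, −0.19), Acrv1 (272 ± 21.6, 0.07) and Adgre1 (1.337 ± 0.354, −0.39) did not pass. Insl3, Hsd3b1 and Star were lower and passed when STZ replicate 1 was left out. The largest decreases after Spp1 were in Bpifa2 (−4.03), Serpina3n (−3.76), Apod (−3.37), Gpnmb (−3.33), the complement gene C3 (−3.15), Timp1 (−3.12) and Lrg1 (−3.07). After Prm2 the largest increases were in Cd5l (0.99), Crmp1 (0.95), Cyp2a12 (0.9), Cldn34d (0.86), Prm1, Prm3 (0.77) and Tmed6 (0.76). In all, 8011 genes differed (limma; 1703 higher, 6308 lower; 5225 with only these groups fitted; 53.4% not overlapping against 10% by chance), and 56.8%, 69.8% and 57.7% of calls were higher after quantile normalization, median centring and the length and GC correction, against 21.3% as deposited.

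The control-donor transplant was the comparator for the donors' AOS. Against STZ, its testes had the same kind of difference in Sertoli and spermatid genes. Clu was at 509.5 ± 30.5 FPKM (log2FC −1.46, SE 0.08, adjusted p = 7.8e-09), Spp1 at 2.013 ± 1.14 FPKM (−4.22) and Prm2 at 11430 ± 1460 FPKM (0.9, adjusted p = 0.00095). Of 26 Sertoli genes 24 fell and 0 rose, also adjusted over the list alone (median −1.01, camera adjusted p = 4.84e-09; adjusted p = 0.266 with an estimated correlation). Of 29 elongating spermatid genes 28 rose, or 29 adjusted over the list alone, and 0 fell (0.51, camera adjusted p = 2.43e-15; adjusted p = 0.266 with an estimated correlation). Of 18 macrophage genes 14 fell and 1 rose, or 15 and 1 adjusted over the list alone (−1.23, camera adjusted p = 0.00219; adjusted p = 0.46 with an estimated correlation). Leydig genes did not pass (−0.51, 10 lower and 2 higher, also adjusted over the list alone; adjusted p = 0.681), but passed without STZ replicate 1 at a median of −1 and after median centring at −0.2. Without STZ replicates 2 and 3 in turn the median was −0.24 and −0.13, with 5 lower each time and camera pointing up.

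This group also held blood and epididymal transcripts. The largest increases against STZ were in the haemoglobin genes Hbb-bs (60.84 ± 51.1 against 2.22 ± 2.74 FPKM, log2FC 3.89) and Hbb-bt (2.35), the defensin gene Defb47 (94.53 ± 158 against 0.1667 ± 0.215 FPKM, 3.88) and Adam7 (2.92), a gene of the epididymis. Adam7 was not called without replicate 3 of the group, and neither Adam7, Defb47 nor Hbb-bt was called with only these groups fitted. The Defb47 mean came mostly from replicate 3 of the group, at 276.78 FPKM, against at most 4.75 FPKM outside the 3 libraries with epididymal transcripts. Control-transplant replicate 1, not among those 3, also held some: Gpx5 was at 5.71, Defb20 at 2.9 and Lcn8 at 1.3 FPKM. In the other groups these genes reached at most 0.17, 0.73 and 0. Crisp1, at 0.99 FPKM, did not stand out in that replicate. Of 8 epididymis genes 2 rose and 1 fell, also adjusted over the list alone (median 1.16, camera adjusted p = 0.026; adjusted p = 0.316 with an estimated correlation). Of 6 erythrocyte genes 2 rose and 1 fell, the same adjusted over the list alone (1.04, camera adjusted p = 0.0407; adjusted p = 0.342 with an estimated correlation). Neither list passed after the 3 other scalings, and leaving out STZ replicate 1 (erythrocyte median 0.19) or STZ replicate 2 (epididymis median 0.96) also ended the respective call. Hist1h3i (listed at 0 in all 3 STZ libraries), Sgca (1.07), Abcc3 (1.07) and Hist1h2aa (0.99) completed the largest increases, and Hist1h3i was not called without STZ replicate 3 or control-transplant replicate 1.

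Decreases in the control-transplant group against STZ were led by Spp1, Bpifa2 (−3.95), Serpina3n (−3.49), Timp1 (−3.03), Gpnmb (−3.02), Ly6d (−3, not called with only these groups fitted), Lrg1 (−2.93) and Itih3 (−2.72). Sox9 (3.33 ± 0.336 FPKM, −1.23), Stra8 (9.46 ± 0.722, −0.97), Kit (5.18 ± 0.296, −0.75) and C1qa (7.78 ± 0.783, −1.53) fell, while Insl3 (2970 ± 549, −0.99), Hsd3b1 (94.77 ± 30.3, −0.53), Star (36.33 ± 4.7, −0.2), Cyp17a1 (248 ± 16.1, −0.15), Sycp3 (168.1 ± 17, −0.21) and Acrv1 (271 ± 3.97, 0.07) did not pass. There were 7257 called genes (limma; 1612 higher, 5645 lower; 4184 with only these groups fitted and 4245 without control replicate 3 and control-transplant replicates 2 and 3). Groups did not overlap for 49.2% of genes, against 10% by chance. The share of calls that were higher was 22.2% as deposited and 54.9%, 70.3% and 57.2% under the 3 other scalings.

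Because STZ vs control and the 3 comparisons against STZ share the same STZ libraries, opposite fold changes between them arise partly from those libraries alone. Across genes, which are not independent replicates, the Pearson correlations with STZ against control were −0.909 for STZ + AOS, −0.933 for the AOS transplant and −0.922 for the control transplant. Simulated data with no true differences gave −0.497 (−0.569 to −0.427 over 100 simulations). The covariances were −0.184, −0.194 and −0.182, against −0.0107 in the simulations. The simulations held no shift shared by the STZ libraries, so they cannot separate such a shift from an effect of the treatments. Of 6118 genes higher in STZ than control, 5482, 5623 and 5283 were lower again in the treated groups, where independent lists would give 2637, 2725 and 2438. The counts for independent lists make no allowance for the shared STZ libraries, and no overlap was simulated. Of 1705 genes lower in STZ, 1284, 1247 and 1219 were higher again.

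**Figure D3:**
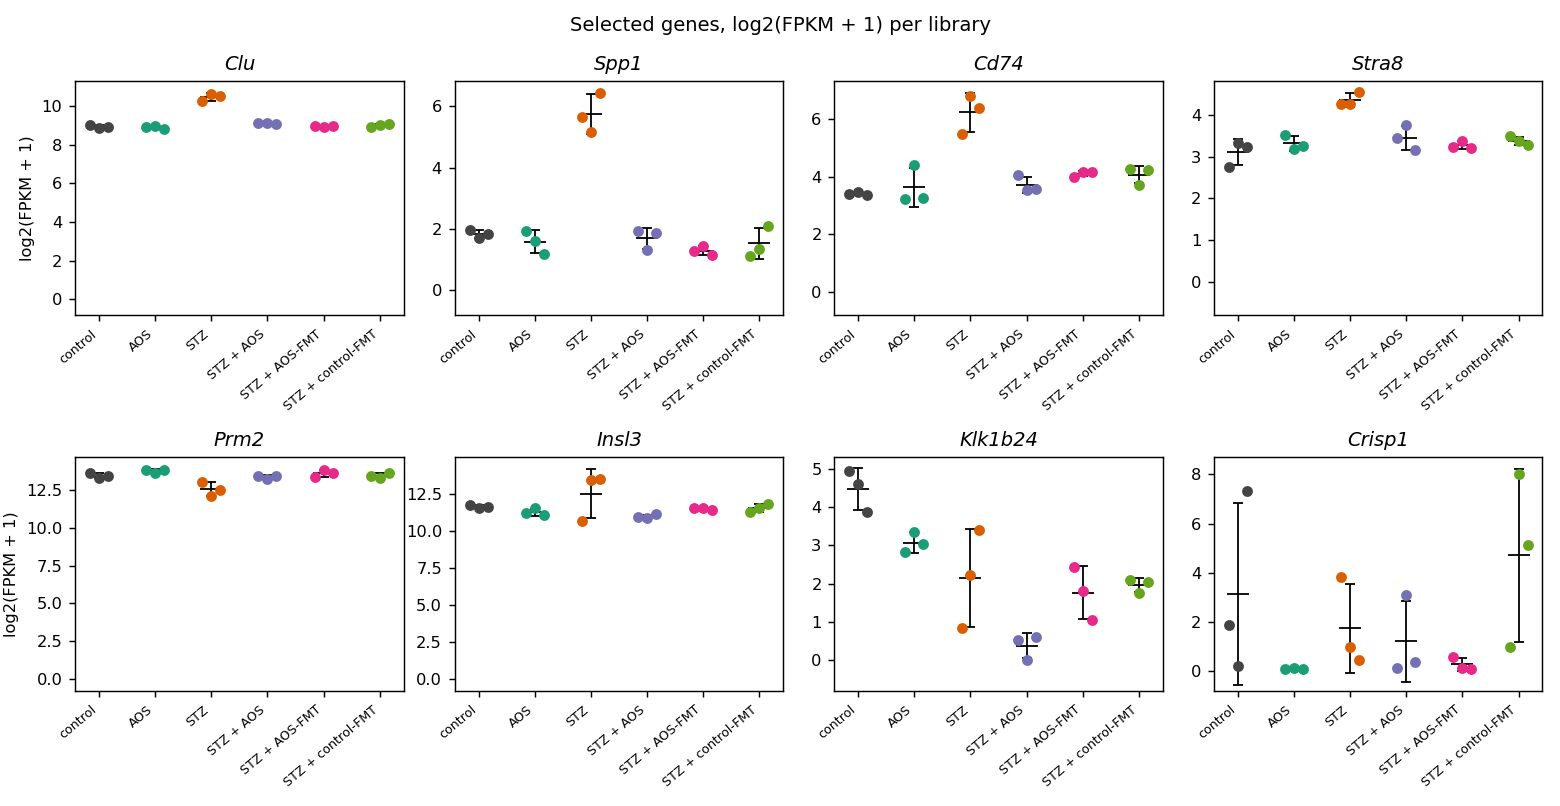
Log2(FPKM + 1) of 8 genes in each library (points), with group means (bars) and SD (whiskers, n = 3). Clu, Spp1, Cd74 and Stra8 are highest and Prm2 lowest in the STZ libraries, Insl3 splits the STZ libraries (1574, 10966.6 and 11438 FPKM), and Crisp1 stands out in single control and control-transplant libraries.

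The series is about the transplant from AOS-dosed donors, so the 2 transplant groups were compared with each other. No gene passed the test between them: limma called 0 genes, with 866 at an unadjusted p under 0.05 and a smallest adjusted p of 0.139. Imp3 had the smallest p (10.83 ± 1.67 in the AOS-transplant and 15.76 ± 0.575 FPKM in the control-transplant group, log2FC −0.51), followed among lower genes by the matrix gene Lum (lumican, −0.6), Mettl9 (−0.25), the creatine kinase gene Ckb (−0.58) and Apod (0.5633 ± 0.217 against 2.963 ± 1.02 FPKM, −1.32). Higher without passing were Ndufaf2 (44.3 ± 2.59 against 34.55 ± 2.35 FPKM, 0.35), Rassf7 (0.27), Mns1 (0.2), Olfr325 (0.46) and Olfr701 (0.31), with adjusted p from 0.34 to 0.55. Clu (−0.05), Sox9 (0.1), Stra8 (−0.11), Zbtb16 (0.05), Sycp3 (0.02), Dmc1 (−0.04), Acrv1 (0), Prm1 (0.04), Tnp1 (0.03), C1qa (−0.09), Adgre1 (0.07), Insl3 (−0.02), Cyp17a1 (−0.08) and Hsd3b1 (−0.22) overlapped between the groups, and Kit (−0.16) and Star (−0.34) did not pass (adjusted p = 0.94 and 0.95). Hba-a1 was at 104 ± 37.2 against 350.7 ± 163 FPKM (−1.71, adjusted p = 0.7) and Crisp1, an epididymal sperm protein gene named after its values were seen, at −4.44 (adjusted p = 0.79).

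Epididymal and blood genes were the lists furthest apart between the transplant groups. The epididymis list had a median of −1.63 (0 called, 5 lower adjusted over the list alone; camera adjusted p = 0.000172, adjusted p = 0.14 with an estimated correlation) and the erythrocyte list −1.59 (0 called, 2 lower adjusted over the list alone; 0.000292, adjusted p = 0.14 with an estimated correlation). Fibroblast (−0.25, 1 lower adjusted over the list alone; 0.000548), myoid (−0.25; 0.0102), adipose (−0.59; 0.0183), immediate early (−0.13; 0.0234), ribosomal (−0.06, 1 lower adjusted over the list alone; 0.0138) and round spermatid genes (0.03; 0.0264) also passed camera with 0 called, and each had adjusted p = 0.911 with an estimated correlation. Without control replicate 3 and control-transplant replicates 2 and 3, the fibroblast, myoid, immediate early, ribosomal and round spermatid lists no longer passed. The ribosomal call also ended after median centring and the length and GC correction, and the round spermatid call after quantile normalization. Leaving out those 3 libraries leaves 1 library in the control-transplant group, assumed to vary like the others. This library, replicate 1, was not free of epididymal or blood transcripts. It had Gpx5 at 5.71 FPKM and an erythrocyte list median of 2.22 relative to control. Groups did not overlap for 14.9% of genes, against 10% by chance. In simulated transplant libraries 66% of genes changed by a log2 of 0.5 and 95.5% of those changed by 1 were called. The simulation gave each gene the same spread in every group. It did not hold the uneven epididymal and blood transcripts, whose lists were shifted here by more than 1 with 0 called. It therefore does not settle which shifts would have been seen in the real libraries.

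The genes that had moved in STZ were also tested as sets between the transplant groups, a contrast that shares no library with STZ against control. The 6118 genes higher in STZ had a median log2FC of −0.065 in AOS transplant minus control transplant, with 4664 lower and 1454 higher, and fry, a rotation test in limma, found no shared direction past the threshold (adjusted p = 0.56 over both sets). The 1705 genes lower in STZ had a median of 0.004 (815 lower, 890 higher; adjusted p = 0.864). Fold changes of the 2 contrasts correlated across genes at −0.144 (Pearson) and −0.3 (Spearman). The median of all genes was −0.034 in this contrast, so part of the split into 4664 and 1454 is common to all genes. After quantile normalization, median centring and the length and GC correction the STZ-higher median was −0.029, −0.039 and −0.04 (all genes: 0.008, 0.018 and 0.011), and without control replicate 3 and control-transplant replicates 2 and 3 it was −0.044. The STZ-higher genes did pass fry, adjusted over both sets, under 2 alternatives, both still with a lower median: when only the groups compared were fitted (−0.072, adjusted p = 0.0234) and without STZ replicate 1 (−0.062, adjusted p = 0.0017). Over all alternatives the adjusted p ranged from 0.0017 to 0.924.

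The interaction asked whether AOS acted differently with and without streptozotocin. With 0 calls for AOS against control and 2 for STZ + AOS against AOS, it rested mostly on the STZ libraries. Sertoli and macrophage genes were among those called. The AOS effect with STZ minus that without was −1.48 for Cldn11 (SE 0.11, adjusted p = 3.6e-06), −1.32 for Clu and −2.13 for Lyz2, and 0.59 for Smcp (adjusted p = 0.0028). Of 26 Sertoli genes 23 had a negative interaction, or 24 adjusted over the list alone, and 0 a positive one (median −1.03, camera adjusted p = 2.02e-09; adjusted p = 0.374 with an estimated correlation). Of 37 motility genes 19 were positive, or 20 adjusted over the list alone, and 0 negative (0.26, camera adjusted p = 1.12e-13; adjusted p = 0.188 with an estimated correlation), with 26 positive without STZ replicate 1 and 11 without STZ replicate 3 (medians 0.29 and 0.19). Hsd3b1 was at −1.59 (adjusted p = 0.032), while Star (−0.84), Cyp17a1 (−0.78) and Insl3 (−1.19) did not pass. The interaction was called for 4984 genes (limma; 867 positive, 4117 negative), with 53.5%, 69.3% and 57.8% positive after quantile normalization, median centring and the length and GC correction, against 17.4% as deposited. The median interaction of all genes was −0.157, and 0.066, 0.151 and 0.059 under these scalings.

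The treated STZ groups were compared with control to see what remained of the STZ difference, comparisons added after seeing the data. The AOS-transplant and control-transplant groups had 0 called genes (limma; 927 and 883 at an unadjusted p under 0.05; 16.7% and 16.3% of genes not overlapping, against 10% by chance). STZ + AOS had 6 called genes (1130 unadjusted), but 76, of which 70 were lower, with only these groups fitted and 135 with array weights. Klk1b24 was at 0.3233 ± 0.284 against 22.25 ± 8.02 FPKM (log2FC −4.1, SE 0.48, adjusted p = 0.0041), Klk1b21 at −4.21 and Klk1b27 at −3.5 (both adjusted p = 0.0076), the glutathione transferase gene Gsta3 at 11.01 ± 1.51 against 32.29 ± 8.06 FPKM (−1.45, adjusted p = 0.02), Iglon5 at 0.69 (adjusted p = 0.02) and Aplp1 at 10.08 ± 0.619 against 5.027 ± 0.527 FPKM (0.88, adjusted p = 0.034). None of these calls held without control replicate 1 or without STZ + AOS replicate 2, when limma called 0 genes. The Klk1b24 and Klk1b27 differences from control in the AOS-transplant (−2.71, −2.62) and control-transplant (−2.51, −2.26) groups did not pass. In AOS without streptozotocin these 2 genes were at 7.5 ± 1.6 and 5.047 ± 1.39 FPKM, also below the control means and also without passing. Next in p in STZ + AOS, without passing, were Klk1b22 (−1.83), Vill (0.59), Ctgf (0.88) and Grb7 (0.64), and in both transplant groups Grb7 (0.72 and 0.75), Klk1b16, Klk1b21 and Klk1b22.

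Leydig genes were the list furthest below control in STZ + AOS. Of 27 members 2 fell and 0 rose, or 9 and 2 adjusted over the list alone (median log2FC −0.66, camera adjusted p = 1.84e-10; adjusted p = 0.913 with an estimated correlation). Star (17.81 ± 6.4 against 44.48 ± 7.68 FPKM), Cyp17a1 (125.2 ± 50.9 against 348 ± 36.1 FPKM) and Hsd3b1 (41.26 ± 14.3 against 71.18 ± 9.17 FPKM) lay below every control library without passing the test (adjusted p = 0.35, 0.42 and 0.61). Cholesterol synthesis genes had a median of −0.31 (0 called, 4 lower adjusted over the list alone; camera adjusted p = 3.75e-08) and Sertoli genes 0.17 (0 called, 3 higher adjusted over the list alone; 2.89e-05), both with adjusted p = 0.913 with an estimated correlation. In the control-transplant group, erythrocyte (1.64; 0 called, 4 higher adjusted over the list alone; adjusted p = 0.139 with an estimated correlation), adipose (0.91; 3 higher; 0.696) and epididymis genes (0 higher; 0.267) passed camera with the preset correlation.

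Streptozotocin was also compared with its absence in AOS-dosed mice, by STZ + AOS against AOS. Cyp2c55, a cytochrome P450 gene, was higher (12.62 ± 0.306 against 9.767 ± 0.363 FPKM, log2FC 0.34, adjusted p = 0.036) and Thrsp, a lipogenic gene, lower (0.49 ± 0.156 against 3.893 ± 1.79 FPKM, −1.66, adjusted p = 0.036). These 2 were the only calls (limma; 1781 at an unadjusted p under 0.05; 24.5% of genes not overlapping against 10% by chance), and 1 or 0 genes passed when any single library was left out. Neither was called with only these groups fitted, when 11 other genes were, or with the replicate number as a block, while array weights gave 224 calls, these 2 included. Next came Ifitm1 (0.67), Aplp1 (0.72), Ctgf (0.84) and Plekhd1 (0.53), and Tgfbr3l (−0.7), Nrep (−0.46), Klk1b24 (−2.69) and Ccr4 (−0.77), none past the test (adjusted p from 0.1 to 0.15). Leydig genes had a median of −0.51 (0 called, 2 lower adjusted over the list alone; camera adjusted p = 1.09e-07; adjusted p = 0.892 with an estimated correlation).

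How far each treated STZ group lay from the AOS group along the STZ minus control difference was measured as a slope over the 7823 called genes. AOS was the baseline because its difference from a treated group shares no library with STZ minus control, although the transplanted mice were not dosed with AOS. The slope was 0.099 for STZ + AOS (0.073 to 0.122 when 1 library was left out), 0.046 for the AOS transplant (0.036 to 0.061) and 0.145 for the control transplant (0.125 to 0.167). It includes any offset of AOS from control and is therefore not the share of the STZ difference that is left. On the first principal component the AOS libraries lay between −16.2 and −12 and the control libraries between −10.1 and −8, on the side away from STZ. Differences of 0, 0.5 and 1 of the STZ difference were simulated for STZ + AOS only, without such an offset. They gave slopes of −0.002, 0.47 and 0.917, over the 8234, 8167 and 8179 genes called in the simulated data. The transplant groups were not simulated. The differences between the 3 slopes were not tested.

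**Figure D4:**
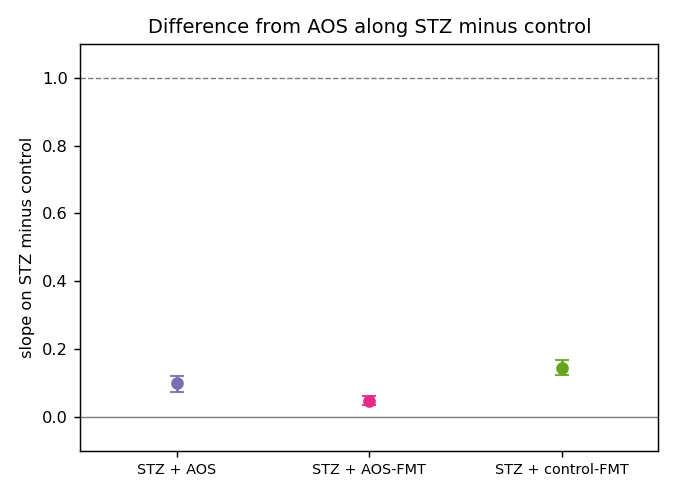
Slope of each treated STZ group's difference from AOS on the STZ minus control difference (y axis, no unit), over 7823 genes, with whiskers from the lowest to the highest slope when 1 library is left out. The slopes are 0.099 (STZ + AOS), 0.046 (AOS transplant) and 0.145 (control transplant) and include any offset of AOS from control. For STZ + AOS, the only group simulated, putting in the whole difference gave 0.917 over 8179 genes (dashed line at 1).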

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

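The tests of the 3 patterns weighed here were chosen only after the results were seen, the length and GC correction among them, and the count of other splits was set beforehand.

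The test of the interaction, the AOS effect with streptozotocin minus that without, called 4984 genes. By limma, AOS against control had 0 calls and STZ + AOS against AOS had 2, so the interaction rested mostly on the STZ libraries. The control-transplant group, not dosed with AOS, differed from STZ in 7257 genes, against 7786 for STZ + AOS. The count therefore does not show an action of AOS particular to mice with streptozotocin. Of the genes named, the difference was positive in Serpini2 (1.18), Hist1h2aa (1.04), Tubb6 (1.03), Spdye4c (0.81), Lmo7 (0.77), Asb4 (0.75), Cyp2a12 (0.75) and Muc1 (0.73). It was negative in Spp1 (−3.78), Bpifa2 (−3.54), Gpnmb (−2.93), Ly6d (−2.86), Cd74 (−2.73), the protease gene Mmp12 (−2.7), Mgp (−2.56) and Wfdc18 (−2.52). Lists with a difference past camera had median differences of −1.31 (interferon response), −1.27 (macrophages), −1.03 (Sertoli cells), −0.91 (immediate early and heat shock genes), −0.67 (blood-testis barrier), −0.61 (retinoic acid), −0.61 (apoptosis), −0.59 (endothelium), −0.57 (fibroblasts) and −0.43 (ribosomal proteins). Spermatogonial genes were at −0.51, but not past the test after quantile normalization, after the length and GC correction or without STZ replicate 1. Oxidative phosphorylation genes were at −0.27, but at 0.04 after median centring and 0 after the length and GC correction. Motility (0.26), elongating spermatid (0.37), round spermatid (0.21) and meiotic genes (0.02, or −0.04 without STZ replicate 1) went the other way. The elongating spermatid median was 0.58 without STZ replicate 1 (24 called), 0.2 without replicate 2 (2 called) and 0.32 without replicate 3 (2 called). Of the motility genes 19 were called, but 26 without STZ replicate 1 and 11 without replicate 3, and of the round spermatid genes 8, but 15 and 2. The fibroblast median was −0.89 without STZ replicate 1, the endothelial list did not pass without STZ replicate 2 or 3, and the oxidative phosphorylation list did not without STZ replicate 3. None of these lists passed with an estimated correlation (adjusted p from 0.188 to 0.508). In 100 splits of the 12 libraries into 4 groups, 2 gave as many genes, the real one included, and the other (5016 genes) was the only one drawn that kept the 3 STZ libraries together. Splits that parted them gave at most 7. The share of 2 in 100 argues against a chance division of all 12 libraries, but it follows how rarely a split keeps the 3 STZ libraries together. It says nothing about whether AOS acted differently with streptozotocin.

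The first pattern is the rise of Sertoli genes with the fall of elongating spermatid genes in STZ libraries (list medians −0.09, −0.84 and −0.56 for the latter). Loss of late spermatids alone would raise the remaining cell types alike, but Sertoli medians exceeded meiotic medians by at least 0.81 in each STZ library, which argues against it as the whole cause. A length or GC bias is argued against by a Sertoli minus elongating spermatid difference of 1.56 after the correction and 1.65 before. A batch shared by the STZ libraries alone, which no label names, cannot be told apart from streptozotocin given without AOS or a transplant. Both would hold the same libraries, and the 0 libraries of other groups with a Sertoli median in the STZ range only restate the pattern. The pattern did not follow streptozotocin as such. Sertoli medians in the treated STZ groups, which also received streptozotocin, lay between 0.01 and 0.17. A changed cell composition or Sertoli cell state after streptozotocin given alone remains a hypothesis.

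The second pattern is that Leydig genes lay below control in STZ replicate 1 and above it in STZ replicates 2 and 3. Less interstitial tissue in replicate 1 than in control would lower macrophage and endothelial genes too. Both list medians were at least 0.18 above the highest control library, although its fibroblast list was at 0 and its erythrocyte list at −1.08. Both lists were higher still in STZ replicates 2 and 3 (macrophage 1.49 and 1.36 against 0.63, endothelial 0.77 and 0.73 against 0.27). The test therefore cannot exclude less interstitial tissue in replicate 1 than in replicates 2 and 3. A milder form of the same change would place the Leydig median of replicate 1 at or above control, and it was −0.41 below the lowest control library. Differences between animals in the state of Leydig cells were not tested and may remain, and no biological explanation is given by the design.

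The third pattern is the set of epididymal genes in single libraries. In control-transplant replicate 3, 10 of 18 members that were low elsewhere reached 10 FPKM or more, including Gpx5 (202.92), Defb20 (99.07), Cst11 (77.81), Lcn9 (76.7) and Lcn8 (70.21), which is what epididymal tissue in that sample would give. In control replicate 3 and control-transplant replicate 2 at least 2 of 18 did so, with Crisp1 at 158.77 and 255.65 and Wfdc15b at 12.76 and 20.49 FPKM. The members Adam7 (8.62 and 10.65), Rnase9 (5.42 and 6.29) and Pate1 (2.71 and 2.1) were also raised there, whereas Gpx5 (0 and 0.38) and Lcn8 (0 and 0.13) were not. Epididymal tissue cannot be told apart from other sources by so few members at 10 FPKM or more of a list written beforehand. Other genes were also far above the 15 remaining libraries there (Defb38 at 19.88 and 27.96 against 0, Spink8 at 42.56 and 61.71 against 4.34 FPKM), but these, like the genes named above, were picked from these libraries and decide nothing. No biological explanation was tested.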

How the results depend on the processing

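Median centring, the length and GC correction and leaving out the libraries with epididymal transcripts were chosen after the results were seen, as were the comparisons of the treated STZ groups with control and of STZ + AOS with AOS. For these alternatives and comparisons together, and for those set beforehand, 5166 and 10086 values of named genes kept direction and call, 187 and 315 lost the call, 100 and 106 gained it and 13 and 5 reversed; for lists, 237 and 480 values kept theirs, 9 and 6 lost the call, 14 and 36 gained it and 1 of the former reversed. Depth varied little, from 0.912 to 1.027 of the average library, and its effect on calls was not tested. For each result below that moved or reversed, the cause was not tested, unless fewer libraries or genes entered by construction.

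With only the groups compared, fewer libraries set the spread: 5132 (STZ against control), 4944 (STZ + AOS against STZ), 5225 (AOS transplant against STZ), 4184 (control transplant against STZ), 76 (STZ + AOS against control) and 11 (STZ + AOS against AOS), and the STZ-higher genes were at −0.072 between the transplants. Array weights gave 22 (AOS against control), 224 (STZ + AOS against AOS), 135 (STZ + AOS against control), 4 (AOS transplant against control) and 9 (control transplant against control). Without a low-value filter the counts were 2 (AOS against control), 4 (STZ + AOS against AOS) and 1 each for both transplants against control and against each other (Chad). Leaving out the libraries with epididymal transcripts gave 4245 (control transplant against STZ), 4 (between the transplants: Defb47, Hbb-bt, Slc12a4 and LOC108168650), 2 (AOS transplant against control), 2 (control transplant against control) and 1 (STZ + AOS against AOS), with 1 control-transplant library left, assumed to vary like the others; the peritubular myoid median between the transplants was 0. The control-transplant library left, replicate 1, itself held epididymal and blood transcripts (Gpx5 at 5.71 FPKM, erythrocyte list median 2.22 relative to control). Median centring gave 12 (STZ + AOS against control), quantile normalization 1 (STZ + AOS against AOS, Thrsp) and the replicate block 0 there by limma, where replicate numbers do not pair the libraries (mean correlation −0.017 over 45 pairs).

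Reversed under median centring were Atp5b (−0.12 in STZ against control, 0.11 in control transplant against STZ), Sdhb (−0.1 in STZ against control, 0.1 in STZ + AOS against STZ, 0.14 in AOS transplant against STZ, 0.02 in the interaction), Dmc1 (0.05 in STZ + AOS against STZ) and Sycp3 (−0.31 in STZ against control). Under the length and GC correction these were Atp5b (−0.05 and 0.02 in the same comparisons), Sdhb (0.02 in STZ + AOS against STZ, 0.01 in the interaction) and Rpl8 (0.03 in the interaction). Under quantile normalization they were Dmc1 (0.09 in STZ + AOS against STZ, 0.04 in the interaction), Insig1 (0.01 in control transplant against STZ) and Prdm9 (0.01 in STZ + AOS against STZ).

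Leaving out single libraries gave 6147 to 8994 genes for STZ against control, 6196 to 8925 for STZ + AOS, 6403 to 9109 for the AOS transplant and 5538 to 8669 for the control transplant against STZ, 3582 to 7235 for the interaction and 5233 to 8781 among all groups, each lowest without STZ replicate 3 and highest without STZ replicate 1. It gave 0 to 1 for AOS against control (1 without control replicate 1, Il3ra), 0 to 3 between the transplants and 0 to 3 for control transplant against control (3 without control-transplant replicate 1), 0 to 1 for AOS transplant against control, 0 to 7 for STZ + AOS against control and 0 to 1 for STZ + AOS against AOS. The STZ-higher genes ranged from −0.075 to −0.05 between the transplants and the STZ-lower genes from −0.006 to 0.019. Star in STZ against control ranged from −0.47 without STZ replicate 3 to 0.6 without STZ replicate 1. Genes named beside these counts were chosen after their values were seen.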

Other observations

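The test on X-linked genes and the counts of other splits of the samples were set before their results were seen.

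The X-linked ribosomal protein genes Rps4x and Rpl10 were 1.53 and 1.29 higher in STZ than control, against a median of 0.38 for the ribosomal list. Since the X chromosome is silenced in meiotic cells, a larger share of RNA from cells with an active X may raise X-linked genes as a class. The median of 634 X-linked genes was 0.33 and that of 13156 autosomal genes 0.17, a difference of 0.16, with 0.09, 0.2 and 0.2 in the STZ libraries and −0.09 to 0.05 in the others. By camera, a limma test, p was 0.127 (0.615 with an estimated correlation), so the hypothesis stays open.

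For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 7823 and 1 (STZ against control), 7786 and 3 (STZ + AOS against STZ), 8011 and 367 (AOS transplant against STZ), 7257 and 815 (control transplant against STZ), 6 and 1 (STZ + AOS against control) and 2 and 1 (STZ + AOS against AOS). In each of these 1 split, the real one, gave as many genes. AOS against control, the transplants against each other and AOS transplant against control had 0 genes by limma in the real split and at most 0 in the others (10 of 10 splits; 1273, 866 and 927 genes at an unadjusted p under 0.05). Control transplant against control had 0 genes by limma (883 unadjusted), while another split gave 31. Which libraries that split put together was not recorded, and the cause was not tested. For any difference among the 6 groups, 1 of 100 splits, the real one, gave as many as 7409 genes, and the highest other gave 5. That share argues against a chance division of all 18 libraries. Whether any of the other splits kept the 3 STZ libraries together was not recorded. The share therefore says nothing about differences among the other groups or about a batch of the STZ libraries.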
